A study of Mus musculus with 4 samples.

How the data were processed

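The data are 4 Clariom S Mouse arrays, 2 of control CD8+ T cell cultures and 2 of cultures with 25 µM spermidine, each made from 250 ng of total RNA. Groups and replicate numbers were taken from the sample titles. The deposited values are log2 signals per feature that the authors made with Affymetrix Expression Console and RMA, per the submitters' processing notes, which give no versions. RMA corrects background, normalizes arrays by quantiles and summarises the probes of a feature, so differences of dim features are compressed. The log2 base and the scale were inferred from the values, which run from 1.72 to 19.93 in gene features. The highest values flatten near the top of each array (19.93, 19.93, 19.87 and 19.74) and 188 features exceeded 16 on every array. Whether signals were rescaled before or within RMA stays unknown, and differences of the brightest features are compressed. The genome build of the annotation is not given in the sources used here, so no coordinates are printed.

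The value table held 28846 features. Of these, 6640 control features were kept out of the gene tests and 22206 gene features were tested. The platform annotation gave 19572 features 1 gene symbol, 0 several symbols and 2634 none, and the symbols stood for 19505 distinct genes. The symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only: 19572 were found and 0 changed. There is no sequencing depth for arrays, and their number limits the precision. No detection call was used here; the antigenomic background features, whose probes match no genomic sequence, had a 95th percentile of 6.35 on average, and gene signals below it may hold little specific signal.

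Spermidine was compared with control feature by feature in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on the deposited log2 values, constant prior, 5.96 prior and 2 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all 22206 features and a threshold of 0.05. The median standard error of a log2 difference was 0.246. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so none was used. The 38 gene lists, 1320 gene names in all, the rule for named genes and the alternatives were fixed before the data were examined. Names were matched to symbols directly or through an unambiguous synonym, and 1108 were measured. Lists were tested with limma's camera on 1 feature per gene, the brightest, with a preset correlation of 0.01 between genes. The adjustment was over the 37 lists with at least 5 measured members. The list of sex-linked genes had too few and was not tested; its measured genes Uty, Kdm5d and Eif2s3y differed by 0.28, 0.24 and 0.06 (log2) at levels below background. Camera with an estimated correlation, camera on ranks and fry were alternatives. Beside each list the members passing over all genes and those passing when adjusted over the list alone were counted.

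Named genes were drawn from features with 1 symbol, leaving out predicted genes, microRNA, snoRNA, olfactory and vomeronasal genes and antigen receptor segments. Both spermidine arrays had to lie on the same side of both control arrays, and the higher group mean had to reach the median feature level of 5.17. The 12 largest higher and 12 largest lower values were taken, called genes before others, together with up to 4 members of each list with the largest statistics and 16 genes fixed by name, 14 of which were measured. Amd1 and Tcf7 were not analysed here.

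The gene test was checked on simulated data with the real means of the 22206 features, in 20 simulations with 200 changed features each. Variances were drawn from the prior that limma fitted, noise was normal and independent, and changed features came from those above the median level. The test recovered 5.52% of 2-fold, 87.6% of 4-fold and 99.2% of 8-fold changes, and 4.91% of its calls were false. These rates hold under the model that the test assumes and do not cover differences shared across features. The list test was checked with the cholesterol synthesis list shifted by -0.5, on genes simulated as independent. That list was called in 20 of 20 simulations, with 0 of 720 calls among the other lists. The check does not cover lists whose genes are correlated. Alternatives were a prior variance with an intensity trend, a robust prior, array weights, a further quantile normalization, median centring, cyclic loess, filters at the median and lower quartile of feature level, 1 feature per symbol, the replicate number as a block, looser thresholds, and leaving out each array in turn.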

Results

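CD8+ T cells were taken from the spleen and lymph nodes of C57BL/6 mice and activated in vitro for 3 days. The stimulus was a set of beads carrying antibodies to CD3 and CD28, which engage the T cell receptor complex and its co-stimulatory receptor, with interleukin 2 in the medium. In the treated cultures 25 µM spermidine, a polyamine, was added to the medium. RNA from 2 control and 2 spermidine cultures was hybridised to Clariom S Mouse arrays, which carry 22206 gene features, and signals were compared as log2 values. Array medians lay between 5.13 and 5.25, and correlations across features between any pair of arrays ran from 0.989 to 0.994. The number of arrays limits the precision of every comparison. The labels call the arrays of each group biological replicates without naming animals or cultures, so the single-gene p-values measure the spread between these samples only. The list p-values with the preset correlation compare list members with other genes. They hardly take in the spread between arrays and can be very small with 4 arrays. The comparison addressed how gene expression in activated CD8+ T cells differs in the presence of spermidine.

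In the spermidine cultures, heme oxygenase 1 (Hmox1) had the largest difference of the genes selected by rule. Its log2 signal was 10.50 ± 0.20 (SD, n = 2) with spermidine and 7.73 ± 0.28 (SD, n = 2) without, a 6.83-fold higher level. Nqo1, a quinone reductase of the antioxidant response, stood at 6.90 in both spermidine arrays against 5.39 ± 0.06 (SD, n = 2). The control signals of Nqo1 lay below 6.35, the mean 95th percentile of the antigenomic background features, where a difference of signals is no measure of the fold. Genes that act in mitosis were lower: Cdk1, the kinase that starts mitosis, was 3.30-fold lower, the kinetochore gene Cenpk 3.18-fold lower, the spindle gene Tacc3 3.07-fold lower and the spindle checkpoint kinase Ttk 2.93-fold lower.

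These single-gene differences were values and not called changes. Of the 22206 features, 0 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), in either direction. The nearest was Hmox1 with an adjusted p = 0.087, a log2 difference of 2.77 ± 0.25 (SE) and higher signals in 2 of 2 spermidine arrays; the next feature had an adjusted p of 0.394. At an unadjusted p under 0.05 there were 1558 features, where 1110.3 would be found with no change at all. The same arrays split by replicate number gave 1341, and the crossed split 496. With a fold of at least 1.5 as well, 644 features were higher and 701 lower with spermidine, 1345 in all, against 1098 in the split by replicate number and 475 in the crossed split. Without control replicate 1 these became 346 and 449, and without spermidine replicate 1 they became 1061 and 1263. Hmox1 passed the adjusted threshold as the only feature when the prior variance followed intensity (adjusted p = 0.0314), after median centring (0.0283), after cyclic loess (0.0462) and among features above the median level (0.0385). With all 4 arrays its adjusted p ran from 0.0283 to 0.0977 over the alternatives, and without 1 array from 0.192 to 1. In 4063 features both spermidine arrays lay above both control arrays and in 4086 below. Chance gives 3701 features, or 16.7%, in each direction.

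Besides Hmox1 and Nqo1 (log2 difference 1.51 ± 0.22, SE), the genes with the largest higher fitted differences were Jchain, which links immunoglobulin chains into polymers (1.92 ± 0.29), the platelet chemokine Ppbp (1.78 ± 0.46), the metalloprotease Adam8 (1.67 ± 0.25), Skint3 (1.60 ± 0.29), Ttc39c (1.55 ± 0.31), the B cell surface protein Cd180 (1.54 ± 0.28), the chemokine Ccl22 (1.51 ± 0.40), the granzyme Gzmc (1.48 ± 0.44), the G-protein signalling regulator Rgs2 (1.45 ± 0.33) and the receptor subunit Il23r (1.38 ± 0.39). The means of Ppbp, Skint3 and Rgs2 stayed below 6.35 in both groups, and those of Jchain, Ccl22 and Il23r in the control group. Differences are compressed there, so for these genes and Nqo1 the value and its place in the order are of signals at background and no measure of the fold. The largest lower values, after Cdk1 (-1.72 ± 0.39), were those of the cationic amino acid transporter Slc7a3 (-1.72 ± 0.37), Cenpk (-1.67 ± 0.31), Tacc3 (-1.62 ± 0.36), the histone gene H3c8 (-1.60 ± 0.46), Ttk (-1.55 ± 0.23), Dapl1 (-1.55 ± 0.24), the ubiquitin-conjugating enzyme Ube2c of mitotic exit (-1.54 ± 0.44), the histone gene H2ac24 (-1.51 ± 0.38), the fatty acid desaturase Fads2 (-1.50 ± 0.40), the cytokine Il24 (-1.47 ± 0.44) and the kinetochore gene Cenph (-1.45 ± 0.45). Leaving out 1 array moved some of these values by over 1.5 times. Without control replicate 2 Gzmc stood at 0.75 and Il23r at 0.74. Without spermidine replicate 2 the values were 1.14 for Ppbp, 0.86 for Ccl22, 0.96 for Rgs2, -1.12 for Slc7a3, -1.08 for Tacc3, -0.88 for H3c8, -0.87 for Ube2c, -0.99 for H2ac24, -0.92 for Fads2, -0.80 for Il24 and -0.66 for Cenph, which stood at -2.23 without spermidine replicate 1. Apart from Hmox1, the adjusted p of these genes was 0.623 or 0.637. H2ac24 had the same values as another feature and is uncertain, as are other histone genes with near-identical copies.

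**Figure D1:**
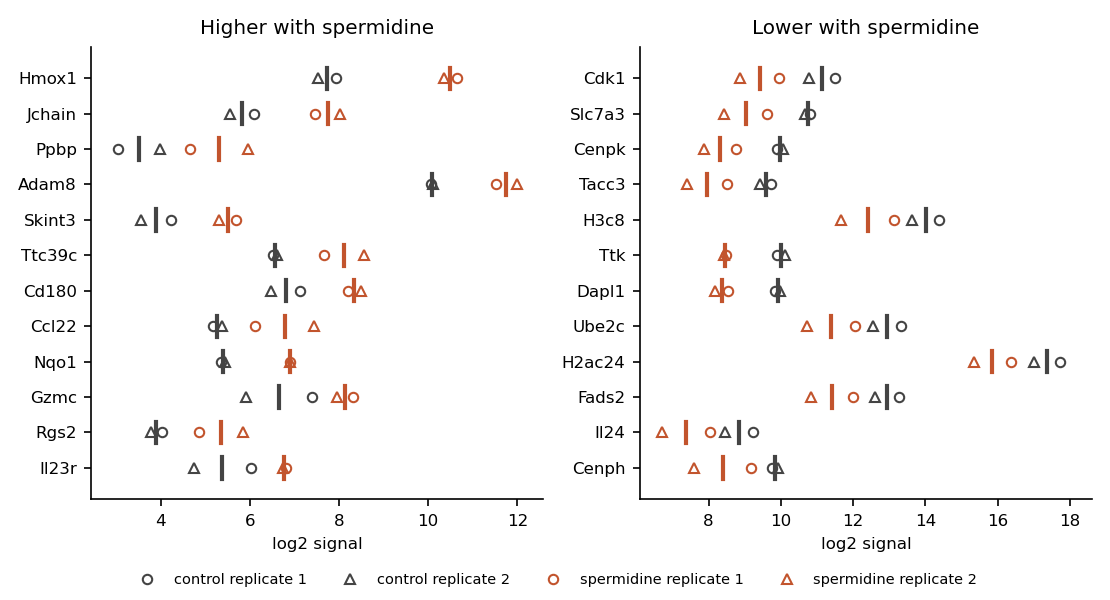
Log2 signal (horizontal axes) of the 12 genes with the largest higher values and the 12 with the largest lower values under the selection rule; each symbol is 1 array and each bar the mean of a group. Hmox1 lay at 10.64 and 10.36 in the spermidine arrays and at 7.92 and 7.53 in the control arrays.

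Genes of cell division were lower together. The mitosis and G2/M list had a mean log2 difference of -0.93 over 69 measured genes, and 68 of them were lower. Its mean was 11.33 and 11.12 in the control arrays and 10.67 and 9.92 in the spermidine arrays. No member passed over all genes, and 48 fell when adjusted over the list alone, among them Ttk, Cenpk, Cdk1 and the mitotic kinase Plk1 (log2 difference -1.27 ± 0.29, SE). The 54 replication-dependent histone genes, which are transcribed during DNA synthesis, had a mean of -0.83. Of these, 39 fell adjusted over the list alone, including H2bc13 (-1.38), H3c13 (-1.38), H2bc3 (-1.12) and H4c14 (-1.09), 1 rose, the linker histone H1f2 (1.10, named after its values were seen), and 0 passed over all genes. The 53 genes of DNA replication and G1/S had a mean of -0.60, and 53 of 53 were lower. The replication factors Gins1 (-0.99), Mcm10 (-0.74) and Mcm3 (-0.75) and the chromatin assembly gene Chaf1b (-0.79) had the largest statistics, and 0 members passed over all genes or adjusted over the list alone. The 3 lists fell against other genes by limma's camera test with a preset correlation (adjusted p = 4.54e-40, 6.39e-30 and 5.77e-20). The calls were lost in the same test with a correlation estimated from the data (adjusted p = 0.507, 0.491 and 0.530 with an estimated correlation). All 3 stayed called without any 1 array, but without spermidine replicate 2 the mean of the mitosis list was -0.56 and that of the G1/S list -0.33. In the same spermidine arrays, and so beside every list difference given here, B cell and macrophage markers had means of 0.34 and 0.20 and the hybridisation spike-ins, control transcripts added to the samples, a mean of 0.451. The count of 48 mitosis genes became 0 without control replicate 1, control replicate 2 or spermidine replicate 2, and the count of 39 histone genes became 0 without control replicate 1 or spermidine replicate 2.

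**Figure D2:**
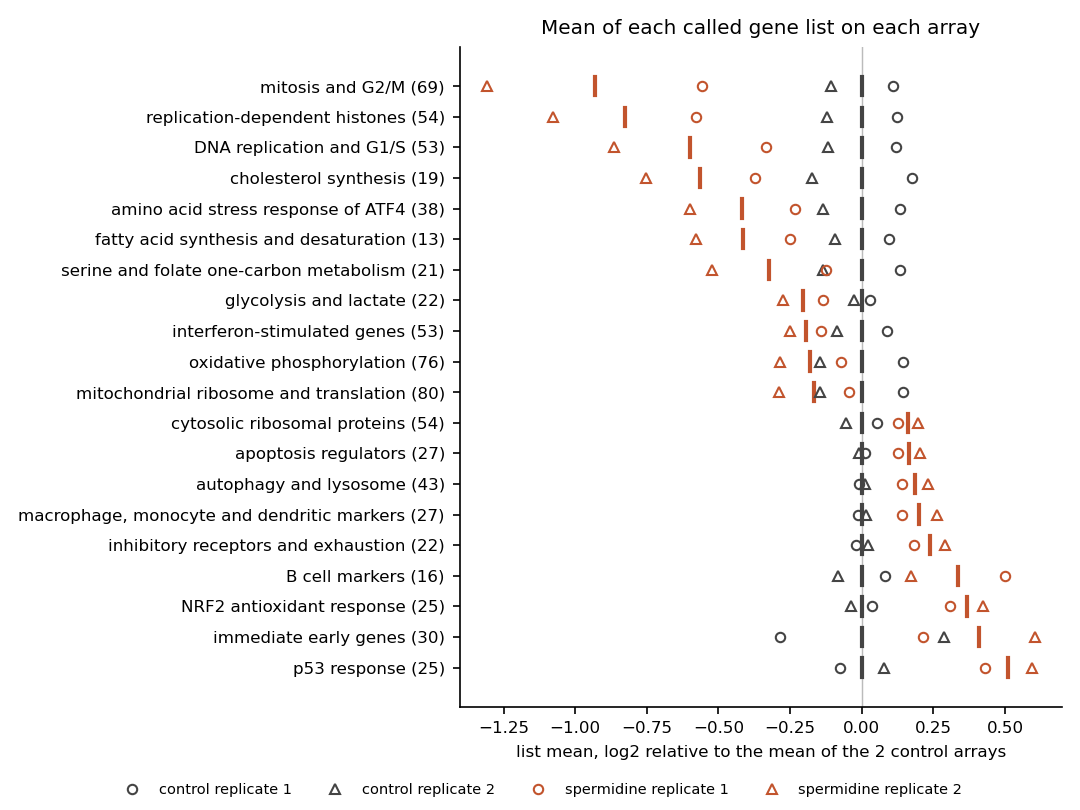
Mean log2 signal of each of the 20 called gene lists on each array, relative to the mean of the 2 control arrays (horizontal axis); symbols are arrays, bars are group means, and the number of measured genes follows each name. For mitosis and G2/M the spermidine arrays differ by 0.75 from each other and the control arrays by 0.22, beside a group difference of -0.93.

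Lipid and amino acid synthesis genes were lower as well. The 19 measured cholesterol synthesis genes had a mean log2 difference of -0.56 and 19 of 19 were lower. Dhcr7, the last reductase of the pathway, fell adjusted over the list alone (-1.30 ± 0.25, SE; adjusted p = 0.0161). The squalene synthase Fdft1 (-0.80), Pmvk (-0.79) and the sterol demethylase Cyp51 (-0.73) did not pass. All 13 genes of fatty acid synthesis and desaturation were lower (mean -0.41), with Fads2 at -1.50, Fads1 at -0.60, Mid1ip1 at -0.59 and Acss2 at -0.44. The 38 genes of the amino acid stress response driven by ATF4 had a mean of -0.42, with 31 lower, among them Slc7a3 (-1.72), the asparagine synthetase Asns (-1.09), the stress protein Nupr1 (-1.02) and the cystathionine lyase Cth (-1.20). The lists fell in camera with the preset correlation (adjusted p = 5.41e-09, 4.18e-04 and 3.02e-07) and the calls were lost with an estimated one (adjusted p = 0.532, 0.491 and 0.540 with an estimated correlation). They stayed called without any 1 array, with means of -0.37, -0.25 and -0.23 without spermidine replicate 2. In the fatty acid and ATF4 lists 0 members passed adjusted over the list alone, and in the 3 lists 0 passed over all genes.

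Central carbon and mitochondrial genes differed by less. The 22 genes of glycolysis and lactate had a mean of -0.21, with the lactate transporter Slc16a3 at -0.88, Aldoc at -0.74, Ldhb at 0.49 and Tpi1 at -0.45. The 21 serine and folate genes of carbon unit transfer had a mean of -0.32, led by Shmt2 (-0.65), Psat1 (-0.56), the thymidylate synthase Tyms (-0.78) and the ribonucleotide reductase gene Rrm1 (-0.63). Without spermidine replicate 2 Tyms stood at -0.31 and Rrm1 at -0.20, and without spermidine replicate 1 at -1.26 and -1.06. The list shared 3 genes with the G1/S list. Shmt2 and Psat1 were also fixed as members of the ATF4 list, as were Phgdh, Psph and Mthfd2, so these lists are not independent. The 76 oxidative phosphorylation genes had a mean of -0.18 (Cyc1 -0.89, Ndufs7 -0.52, Atp5g2 -0.53, Ndufs1 -0.53) and the 80 genes of the mitochondrial ribosome and translation a mean of -0.17 (Mrps18c -0.73, Mrps18a -0.73, Polrmt 0.83, Mrpl4 -0.56). These 4 lists were called lower with the preset correlation (adjusted p = 0.0112, 4.18e-04, 7.05e-04 and 2.75e-03). The calls were lost with an estimated one (adjusted p = 0.530, 0.631, 0.761 and 0.761 with an estimated correlation), and 0 of their genes passed over all genes or adjusted over the list alone. For the last 3 lists the difference was smaller than the gap between arrays of a group, by ratios of 0.821, 0.622 and 0.572. Without control replicate 1 the means were -0.18, -0.19, -0.04 and -0.02, and without spermidine replicate 2 they were -0.13, -0.13, -0.07 and -0.04, in that order; none of the 4 lists was called in either case. Other arrays left out gave means over 1.5 times as large: oxidative phosphorylation -0.32 and the mitochondrial ribosome -0.31 without control replicate 2, and serine and folate genes -0.52, oxidative phosphorylation -0.29 and the mitochondrial ribosome -0.29 without spermidine replicate 1. The citrate cycle (22 genes, mean -0.10, adjusted p = 0.289) and hypoxia response lists (19 genes, mean -0.17, adjusted p = 0.0947) were not called. Without control replicate 2 they were called lower, with means of -0.20 and -0.24, and the hypoxia list also without spermidine replicate 1 (mean -0.29). The hypoxia mean was -0.11 without control replicate 1 and -0.062 without spermidine replicate 2. Their strongest members were Dlst (0.70), Sdha (-0.43), Idh3a (-0.49) and Dlat (-0.38), and P4ha2 (-0.78), Bnip3 (-0.81), Ddit4 (0.42) and Slc2a1 (-0.47). Bnip3 stood at -0.40 without spermidine replicate 2, Idh3a at -0.22 without control replicate 1 and Polrmt at 0.35 without control replicate 2. The means of Polrmt and P4ha2 lay below the background percentile in both groups, P4ha2 with 1 control array above it (6.61).

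The NRF2, p53, autophagy and apoptosis lists were higher. The 25 NRF2 target genes, an antioxidant programme, had a mean log2 difference of 0.37 with 18 higher. Hmox1 (adjusted p = 9.80e-05) and Nqo1 (adjusted p = 1.57e-03) rose adjusted over the list alone, while the efflux pump Abcc1 (0.90 ± 0.29, SE) and the glutathione synthesis gene Gclc (0.70 ± 0.23, SE) did not pass. The 25 p53 response genes had a mean of 0.51 and 25 of 25 were higher. Phlda3 (0.92 ± 0.22, SE) and Trp53inp1 (1.14 ± 0.28, SE) rose adjusted over the list alone (adjusted p = 0.0425 for each), and the antiproliferative gene Btg2 (1.04) and the DNA polymerase Polk (0.73) did not pass. In the 2 lists the group difference was 3.12 times the larger gap between arrays of a group. The 43 autophagy and lysosome genes had a mean of 0.19 with 35 higher; the selective autophagy receptor Sqstm1 stood at 1.09, Atg10 at -0.68, Atg16l1 at 0.68 and the initiating kinase Ulk1 at 0.56. The 27 apoptosis regulators had a mean of 0.17, with Bcl2a1a at 0.82, the cell death inducer Bcl2l11 at 0.84, the death receptor Fas at 0.68 and Casp9 at 0.58. Fas, Bax, Bbc3 and Pmaip1 were fixed as members of both the p53 and the apoptosis list. The 4 lists rose in camera with the preset correlation (adjusted p = 1.06e-04, 4.02e-11, 1.40e-03 and 0.0199), and the calls were lost with an estimated one (adjusted p = 0.491 for each with an estimated correlation). No gene of the 4 lists passed over all genes, and 0 of the autophagy and apoptosis genes passed adjusted over the list alone. The apoptosis list was not called without control replicate 2 (mean 0.15) or without spermidine replicate 2 (mean 0.13). Ulk1 and Casp9 lay below the background percentile in both groups.

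The 30 immediate early genes, which respond within minutes to receptor signals, had a mean of 0.41. Junb stood at 1.02, Btg2 at 1.04, Ier5 at 0.62 and Jun at 1.16, and 0 members passed over all genes or adjusted over the list alone. Jun stood at 0.55 without control replicate 1 and 0.59 without spermidine replicate 2, and at 1.78 and 1.73 without the other array of each group, and its arrays overlapped (12.23 in 1 control and 12.21 in 1 spermidine array). The list was called higher with the preset correlation (adjusted p = 2.38e-06; adjusted p = 0.564 with an estimated correlation). The difference was 0.714 times the gap between the control arrays (8.78 and 9.35), and without control replicate 1 the mean was 0.12 and the call was lost. The mean was 0.69 without control replicate 2 and 0.21 without spermidine replicate 2. The 54 cytosolic ribosomal protein genes had a mean of 0.16, with Rpl37a at 0.71, Rpl36 at 0.59, Rps20 at 0.46 and Rps19 at 0.45. That list was called higher (adjusted p = 7.05e-04; adjusted p = 0.679 with an estimated correlation), not without control replicate 2 (mean 0.11), and 0 members passed over all genes or adjusted over the list alone. The list averaged 16.24 in the control arrays, toward the top of the scale, while the 4 members named here had control levels below 16. Ribosome biogenesis and MYC targets (48 genes, mean -0.03, adjusted p = 0.821), the unfolded protein response (22 genes, mean -0.10, adjusted p = 0.448) and the cytosolic heat shock response (14 genes, mean 0.07, adjusted p = 0.855) were not called. Without control replicate 2 the MYC and unfolded protein lists were called lower (means -0.18 and -0.24). Among their members were Polr1e (0.44), Cdk4 (-0.39), Nop58 (-0.39), Polr1c (0.33), Atf6 (0.69), Sec61b (-0.64), Pdia6 (-0.59), Creld2 (-0.53), Hspa1a (0.95), Dnajb1 (-0.56) and Bag3 (0.45). Without control replicate 1 Nop58 stood at -0.14, Pdia6 at -0.28, Creld2 at -0.19 and Bag3 at 0.22. The heat shock gene Hspa1b rose adjusted over its list alone (1.31 ± 0.31, SE; adjusted p = 0.0450), from control signals below the background percentile, and Bag3 lay below it in both groups.

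Of the lists of CD8+ T cell function, those of inhibitory receptors and of interferon-stimulated genes were called. The 35 effector and cytotoxicity genes had a mean log2 difference of 0.02 and were not called (adjusted p = 0.909). Granzyme B (Gzmb) stood at 17.99 ± 0.14 with spermidine and 17.96 ± 0.10 without (SD, n = 2 each), near the top of the scale. The log2 difference was -0.14 ± 0.24 (SE) for interferon gamma (Ifng) and -0.49 ± 0.32 (SE) for perforin (Prf1). Prf1 stood at -0.16 without control replicate 1 and -0.14 without spermidine replicate 2, and at -0.81 and -0.83 without the other array of each group. The chemokine Ccl3 (1.31), Serpinb6b (0.88), the lectin receptor Klrd1 (-0.89) and Gzmc (1.48) did not pass adjusted over the list alone. The naive and memory list (25 genes, mean -0.18, adjusted p = 0.0987) was not called, except as lower without control replicate 1 (mean -0.24), and had a mean of -0.11 without control replicate 2; Dapl1 fell adjusted over it alone (adjusted p = 4.91e-03), and Ly6c2 (-0.97), the quiescence factor Klf2 (-0.65) and Ly6c1 (-0.86) did not pass. The activation and interleukin 2 signalling list (39 genes, mean -0.06, adjusted p = 0.797) held Lif (-1.0), Gadd45b (1.01), Il24 (-1.47) and Ccnd3 (-0.66). The list of chemokine receptors, integrins and trafficking (29 genes, mean 0.06, adjusted p = 0.448) held Itgb3 (0.80), Klf2, Icam1 (0.68) and Ccr4 (-0.68). The 22 inhibitory receptor and exhaustion genes had a mean of 0.24 and were called higher (adjusted p = 5.80e-03; adjusted p = 0.491 with an estimated correlation), not without spermidine replicate 2 (mean 0.18). Lilrb4a (1.17 ± 0.27, SE) and the signalling regulator Rgs16 (1.03 ± 0.26, SE) rose adjusted over the list alone (adjusted p = 0.0483 for each). The inhibitory receptors Lag3 (-0.66) and Havcr2 (0.65) lay on opposite sides of 0, and Pdcd1 (PD-1) differed by 0.02 ± 0.27 (SE) with signals below the background percentile of 6.35. The 53 interferon-stimulated genes had a mean of -0.20 and were called lower (adjusted p = 1.96e-03; adjusted p = 0.540 with an estimated correlation), not without control replicate 1 (mean -0.11). Psmb9 (-0.97), Mx1 (1.0), Ifit3 (-0.78) and Xaf1 (-0.89) did not pass adjusted over that list alone. The control means of Gadd45b and Rgs16 and the spermidine mean of Lag3 also lay below that percentile, Rgs16 with 1 control array above it (6.44).

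Polyamine and fatty acid oxidation genes, which handle spermidine and mitochondrial fat use, were not called as lists. The 23 polyamine genes had a mean of -0.07 (adjusted p = 0.513). Odc1, the enzyme that opens polyamine synthesis, differed by 0.13 ± 0.25 (SE), the catabolic acetyltransferase Sat1 by 0.07 ± 0.22 (SE) and the spermine oxidase Smox by 0.45 ± 0.23 (SE); Azin1 (-0.51), Sms (-0.42) and Oaz2 (-0.39) did not pass. The 32 fatty acid oxidation genes had a mean of 0.01 (adjusted p = 0.851). Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein, stood at 13.12 ± 0.08 and 11.85 ± 0.14 with spermidine and at 13.12 ± 0.14 and 11.91 ± 0.05 without (SD, n = 2 each). The values for Cpt1a, Acadvl, Acad10, Cpt2 and Acsl5 were -0.19, 0.49, 0.67, -0.51 and -0.49. No gene of the 2 lists passed over all genes or adjusted over the list alone. The transcription factor Myc differed by 0.12 ± 0.26 (SE) and stood at 16.85 and 17.14 in the control arrays. Acad10 and Cpt2 lay below the background percentile in both groups.

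**Figure D3:**
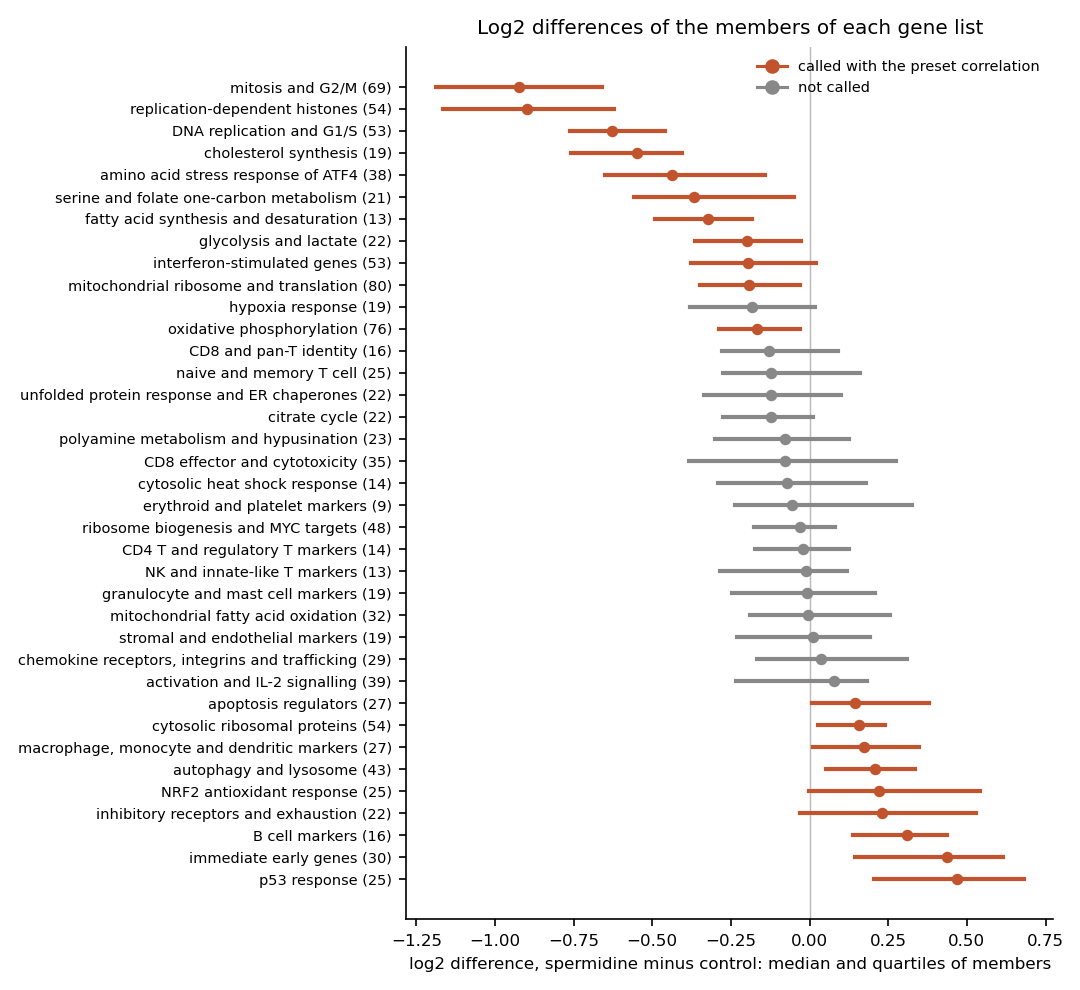
Median (point) and quartiles (line) of the log2 differences, spermidine minus control (horizontal axis), of the members of each of the 37 tested lists; coloured lists were called in camera with the preset correlation, and the number of measured genes follows each name. The mitosis and G2/M median is -0.92 and the p53 response median 0.47.

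The T cell identity list was not called, and B cell and macrophage markers were higher. The 16 measured genes of CD8 and pan-T identity had a mean of -0.06 (adjusted p = 0.616), with Cd8a at 16.58 ± 0.01 and 16.67 ± 0.01 (SD, n = 2 each), Cd28 at a log2 difference of 0.43, Thy1 at -0.36, Cd6 at 0.41 and Cd8b1 at -0.34. The 16 B cell markers had a mean of 0.34 and 15 were higher, with Cd79a at 0.81, Cd22 at 0.94, Ebf1 at 0.52 and H2-Aa at 0.41. The list was called higher (adjusted p = 3.16e-04; adjusted p = 0.540 with an estimated correlation), not without spermidine replicate 1 (mean 0.17). The 27 macrophage, monocyte and dendritic markers had a mean of 0.20 and were called higher (adjusted p = 0.0112; adjusted p = 0.491 with an estimated correlation), not without control replicate 1 (mean 0.19) or spermidine replicate 2 (mean 0.14). The oxidase subunit Cybb rose adjusted over that list alone (1.03 ± 0.22, SE; adjusted p = 0.0489), from a control level of 6.30, below the background percentile, and Ccl22, Lyz2 (0.86) and Fcgr1 (-0.50) did not pass. The 2 lists shared 3 genes, and 6 of the 27 macrophage markers exceeded the background percentile. Markers of granulocytes and mast cells (19 genes, mean 0.05, adjusted p = 0.797), NK and innate-like T cells (13, 0.02, 0.909), CD4 and regulatory T cells (14, -0.05, 0.851), erythroid cells and platelets (9, 0.14, 0.851) and stroma and endothelium (19, 0.05, 0.797) were not called. Their leading members were Gata2 (0.75), Cpa3 (0.73), Cxcr2 (-0.59) and Kit (0.69), then Il23r, Klra3 (-0.93), Ncr1 (0.44) and Sox13 (-0.29), then Zbtb7b (0.76), Ikzf4 (-0.71), Ccr4 and Tnfrsf4 (-0.44), then Ppbp, Slc4a1 (-0.62), Alas2 (0.33) and Gata1 (-0.32), then Vwf (1.13), Pdgfrb (0.72), Emcn (0.39) and Krt8 (-0.33). Without spermidine replicate 2 Kit stood at 0.096, Ikzf4 at -0.33, Alas2 at 0.10, Gata1 at -0.097, Emcn at 0.18 and Cd6 at 0.17, and without spermidine replicate 1 Kit stood at 1.27. The erythroid and platelet mean was 0.0025 without spermidine replicate 2 and 0.013 without control replicate 1. It was 0.27 without spermidine replicate 1 and 0.26 without control replicate 2. Of the leading members of these 5 lists only Ppbp passed adjusted over its list alone (adjusted p = 0.0402). Cd22, Lyz2, Fcgr1, Gata2, Cxcr2, Klra3, Ncr1, Sox13, Ppbp, Alas2, Pdgfrb, Emcn and Krt8 lay below the background percentile in both groups, Ccl22, Il23r and Vwf in the control group and Slc4a1 in the spermidine group. Cd4 differed by -0.06 ± 0.28 (SE). In 7 of the lists not called the mean and the median had opposite signs, so the means given for them show no direction. The medians were -0.0043 for fatty acid oxidation, -0.071 for heat shock, -0.077 for CD8 effector and 0.076 for activation genes. For granulocyte, NK and erythroid markers they were -0.0083, -0.012 and -0.056.

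In all, 20 of 37 lists were called with the preset correlation, 9 higher and 11 lower, 20 by camera on ranks, and 0 with an estimated correlation or by fry. Outside the mitosis and histone lists 11 genes passed adjusted over a list alone. Of these, Hmox1 and Nqo1 still passed without any 1 array, and Cybb lost its call without each of the 4 arrays. Dapl1 lost it without either control array, and Dhcr7, Phlda3, Trp53inp1, Hspa1b, Rgs16, Lilrb4a and Ppbp kept it when spermidine replicate 1 was left out and lost it without any other array. In data simulated with independent genes the cholesterol list, shifted by -0.5, was called in 20 of 20 runs with the preset correlation. With an estimated correlation it was called in 0 of 20, and other lists and shifts were not simulated. In the real data the estimated correlation was 0.518 for that list and 0.67 for the mitosis list, against a preset 0.01. The simulation therefore does not show how either test performs on correlated genes. The preset test also called 16 lists when the same arrays were split by replicate number, and 1 list in the crossed split. The mitosis list was called in all 3 splits, lower in replicate 2 (adjusted p = 1.54e-07) and higher in the crossed split (adjusted p = 0.00632). Of the 168 genes selected by rule, 78 changed sign or moved by over 1.5 times without at least 1 of the arrays, 57 of them without spermidine replicate 2.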

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

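The control features outside the gene comparison differed between the groups. All 4 hybridisation spike-ins, bacterial and phage transcripts added in fixed amounts, were higher on both spermidine arrays than on both control arrays, by 0.562 (bioB), 0.456 (bioC), 0.476 (bioD) and 0.311 (cre) on the log2 scale, and 3 of the 4 poly-A spike-ins were likewise higher, by 0.495 (dap), 0.419 (lys) and 0.424 (phe). The poly-A spike-in thr differed by 0.372 with overlapping arrays, and none of these differences was tested. The signals of lys, phe and thr lay below the background percentile of 6.35 on every array, where a difference is no measure of the fold. Of the poly-A spike-ins only dap exceeded it.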

How the results depend on the processing

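Alternatives with cell cycle and histone genes left out, and with identical histone features counted once, were chosen after the data were seen; the first left 34 lists, in which 17 of 17 called lists stayed called, and the second gave 38 histone genes. With all 4 arrays and the preset correlation, 20 lists were called under every other alternative, and the 20 called lists kept call and direction in 180 of 180 list-by-setting results. For lists, 1 feature per symbol repeats the main test. Array weights were equal within each group (1.09 for control, 0.917 for spermidine), so neither setting adds a check. Between 45 and 59 mitosis and between 39 and 44 histone genes passed adjusted over the list alone. List tests with a robust prior were not run, since camera takes none. The granulocyte, erythroid and stromal lists had under 5 members above the median level and give no value there. With an estimated correlation 0 lists were called and by fry 0. Among single genes 1 passed, Hmox1, which rose, with a prior trend, median centring, cyclic loess, features above the median level, the replicate block or an adjusted p under 0.1, and 0 fell; with the robust prior, array weights, quantile normalization, the lower quartile filter or 1 feature per symbol 0 passed. At an unadjusted p under 0.05 with a fold of 1.5 there were 1345 genes, 644 higher and 701 lower; among features above the median level, with fewer features tested, 364 were higher. Without 1 array in turn, 0 genes passed, 346 to 1061 were higher and 449 to 1263 lower at the unadjusted threshold, 13 to 22 lists were called, and 0 to 60 mitosis and 0 to 42 histone genes passed adjusted over the list alone. In those fits the lone array is assumed to vary like the other group. The replicate numbers share no stated animal or day, and the replicate 1 minus 2 differences of the groups correlated at 0.210 across features, in 2 pairs; with the replicate block 1 gene and 20 lists passed, and 2350 against 1558 features had an unadjusted p under 0.05.

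Some values that were not called with all 4 arrays changed sign, none of them past the threshold at the opposite sign, and the cause was not tested. With quantile normalization they were Cd8a 0.034, Gzmb -0.087, Hadha 0.075, Pdcd1 -0.00093 and the MYC list 0.016, with cyclic loess Hadha 0.053, Pdcd1 -0.00023 and the MYC list 0.017, with median centring the fatty acid oxidation list -0.0051, and above the lower quartile level the NK list -0.030. Without 1 array the ranges were Cd4 -0.39 to 0.27, Cpt1a -0.45 to 0.071, Gzmb -0.064 to 0.13, Hadha -0.10 to 0.10, Hadhb -0.16 to 0.041, Ifng -0.29 to 0.0050, Myc -0.11 to 0.35, Odc1 -0.063 to 0.33, Pdcd1 -0.21 to 0.25 and Sat1 -0.027 to 0.16. For lists they were CD4 T cells -0.11 to 0.0080, CD8 effector -0.11 to 0.14, NK -0.20 to 0.24, citrate cycle -0.20 to 0.0043, granulocytes -0.045 to 0.14, fatty acid oxidation -0.046 to 0.064, MYC targets -0.18 to 0.12, stroma -0.10 to 0.20 and the unfolded protein response -0.24 to 0.045. Without control replicate 2 the citrate cycle, unfolded protein, MYC and hypoxia lists were called lower (adjusted p = 0.0407, 0.0270, 0.0168 and 0.0440), as were the hypoxia list without spermidine replicate 1 (0.0335) and the naive and memory list without control replicate 1 (0.0332). Of the 20 called lists, 9 stayed called without any 1 array. Signal over background limits the B cell and macrophage lists, where 8 of 16 B cell and 6 of 27 macrophage markers exceeded the background percentile.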

Other observations

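The lists of the first paragraphs and the check on markers above background, with the choice to let marker lists mostly at background exclude nothing, were made after the data were seen, and the other tests were set on patterns noticed in single genes, before list values were computed. The 26 genes of homologous recombination and Fanconi anaemia, which repair DNA breaks and crosslinks at replication forks, had a mean log2 difference of -0.46. They were lower as a list with the preset correlation (adjusted p = 8.17e-09 over 4 such lists; adjusted p = 0.272 with an estimated correlation). In 16 of 26 both spermidine arrays lay below both controls, where chance gives 16.7%, and in 0 above. Fancl (-1.13 ± 0.24, SE) passed adjusted over the list alone (adjusted p = 0.0350), while Fanca (-0.88), Fancb (-0.79) and Brip1 (-0.73) did not. The 38 genes of chemokine and cytokine ligands had a mean of 0.13 (adjusted p = 0.150), with members going opposite ways. This list and the one above were made after the data were seen, with Ppbp and Ccl22 already among the largest differences. Passing over such a list alone is no independent support. Ccl3 (1.31), Ppbp (1.78), Ccl22 (1.51) and Il22 (1.03) were higher and the leukaemia inhibitory factor gene Lif (-1.0) lower, and these 5 passed adjusted over the list alone. They and Fancl kept that call when spermidine replicate 1 was left out and lost it without any other array.

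Hmox1 stood apart from other genes of heme and iron handling. The 23 genes of that list had a median of -0.07 and a mean of 0.12 (adjusted p = 0.292). Hmox1 alone passed adjusted over the list (adjusted p = 9.01e-05). The heme transporter Slc48a1 (0.76), the ferritin light chain Ftl1 (0.64) and Uros (0.70) did not. The list was made after the data were seen, when Hmox1 already had the smallest p of all features. Its pass over this list is therefore no further support. The 38 genes of aldehyde and glutathione detoxification had a mean of 0.11 (adjusted p = 0.132), with Aldh2 at 1.10 and Gclc at 0.70, and 0 passed adjusted over the list alone.

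The lower mitosis and G2/M genes may reflect a smaller dividing share or slower division in the spermidine cultures, a hypothesis that these arrays cannot separate from a difference between cultures that has nothing to do with spermidine. A smaller share of T cells as the whole source is argued against. The pan-T list had a median of -0.129 (lower quartile -0.28), above the mitosis median of -0.922 by 0.793. A small loss of T cells is not excluded. The pan-T mean was lower on both spermidine arrays (13.82 and 13.84) than on both control arrays (13.88 and 13.90). Its members Cd8a and Cd8b1 lay toward the top of the scale, where differences are compressed. An intensity-dependent difference between arrays is argued against as well: of 10000 random lists matched on mean log2 value, 0 had a median as low, and their lowest was -0.229. The list stayed called without either spermidine array and its mean was still -0.56 without spermidine replicate 2, so that array is not the whole source, though no mitosis gene then passed adjusted over the list alone. What stays open is culture-to-culture variation, since the mitosis list was called in all 3 splits of the 4 arrays, also lower in replicate 2 than in replicate 1 (adjusted p = 1.54e-07) and higher in the crossed split (adjusted p = 0.00632).

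The higher Hmox1 and Nqo1 signals are consistent with a response shared by other NRF2 targets, as a hypothesis. Without these 2 genes, the remaining 23 had a median of 0.197 and 16 were higher (camera p = 0.00302; p = 0.194 with an estimated correlation), far below the 2.77 of Hmox1. RNA of macrophages and dendritic cells stays open. The macrophage list had a median difference of 0.172 and an upper quartile of 0.347, under the bound set for excluding it, but only 6 of its 27 members exceeded background. Those 6 had a median of 0.341 and an upper quartile of 0.873. Cybb, on the list, exceeded the background percentile only with spermidine (control mean 6.30, spermidine mean 7.33). The same held for the mean of Ccl22, also on the list (control 5.27, spermidine 6.78). A member that passes in that way is bound to be higher, so the values of the 6 are no support for macrophage RNA. Among list members below background, C1qa went from 2.85 to 2.86, Tyrobp from 3.51 to 3.63 and Lyz2 from 3.94 to 4.80, a difference of 0.86. H2-Aa, shared with the B cell list, lay above background in both groups, at 8.13 without and 8.54 with spermidine. Of all 27 members, 21 were higher and 6 lower. A rise of Hmox1 within a few macrophages or dendritic cells, and an action of spermidine through its products in the medium, were not tested.

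Jchain (1.92), Cd180 (1.54), Cybb (1.03) and Lilr4b (1.31) are known from B cells or myeloid cells and were higher together; they were picked after their values were seen. A larger share of B cells and myeloid cells may contribute and stays open. The B cell list had a median of 0.311 and an upper quartile of 0.436, and the macrophage list a median of 0.172, under the bound set for excluding it, but with most members at background. The 8 B cell and 6 macrophage markers above background had medians of 0.378 and 0.341, and all of them were higher. Cybb is among these 6 and also among the 4 genes to be explained, and it exceeded the background percentile only with spermidine. The mean of Ccl22, also on the macrophage list, likewise exceeded that percentile only with spermidine. A marker that passes in that way is bound to be higher, so the direction of the 6 is no support for more myeloid cells. No such check is given for the 8 B cell markers. The B cell and macrophage lists shared 3 genes, so their values are not independent. The medians of 0.378 and 0.341 lie below the 4 differences, but signals near background are compressed. A gain of other cells and expression of the 4 genes in the T cells therefore cannot be told apart.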
